A study of Glycine max with 4 samples.

How the data were processed

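Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on embryos of the soybean cultivar Williams 82 at the early maturation stage, the period in which the seed begins to accumulate storage protein and oil. Per the labels' protocols, the antibody was raised against a peptide of GLYMA.13G317000, and chromatin set aside before immunoprecipitation served as input. The peak names in the deposited files carry BZIP67, the name of a basic leucine zipper transcription factor, which was taken to be the same protein; the labels do not state this. The series holds 4 libraries: 2 ChIP libraries and 2 input libraries, each group from biological replicates numbered 1 and 2 per the labels.

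The analysis began from 2 peak lists, 1 per ChIP library, so peaks had been called separately in each replicate. The submitters' processing notes name Bowtie 0.12.7, a short-read aligner, and MACS2, a peak caller. The genome build and the settings of both programs are not given in the sources used here. The peak names carry a q of 0.01. No processed file of the input libraries was used here, and the input entered only through the deposited values. Whether each ChIP library was set against the input of its own replicate or against pooled inputs is not given in the sources used here, so the local background of a replicate cannot be tied to 1 input library. For each peak, the authors' files give a fold, which is the ratio of the ChIP signal at the summit to the local background. The deposited −log10 p and −log10 q belong to the same summit, and the deposited score equalled 10 times the −log10 q, cut to a whole number, in 100% of peaks of both lists. These values are the authors' own, were made within each library, and were used to rank and filter peaks within a list.

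The number of reads per library is not given in the sources used here. The number of ChIP fragments over each summit (pileup) and the local background were therefore solved from the deposited fold and −log10 p, with a pseudocount of 1 in the fold and the Poisson probability of a higher pileup. A whole-number pileup met both values in 100% of peaks of each list within 0.001 on the −log10 p scale. The next whole number missed by at least 0.0089 in replicate 1 and 0.00804 in replicate 2. Pileups covered 20 to 408 fragments in replicate 1 and 19 to 398 in replicate 2. Exact Poisson intervals at the 95% level are given for the summits of the strongest region. The lowest local background, a floor taken as the genome-wide level, was 7.08 fragments in replicate 1, where 540 peaks lay at it, and 6.26 in replicate 2, where 790 did. The Poisson intervals, and the Wilson intervals of shares of peaks, cover counting error only, and the former assume no upper limit on the pileup.

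A peak counted as shared when it overlapped a peak of the other list by at least 1 bp. Overlapping peaks of both lists were merged into regions, and the strongest peak of each list stood for the region. Chance overlap was taken from 1000 seeded circular shifts of one list within each chromosome or scaffold, with a one-sided permutation p whose smallest possible value is 0.001. Agreement of strength was measured as Spearman and Pearson correlations of the log2 fold across shared regions. Regions are not independent replicates, so no p-value was attached to these correlations. With 2 libraries of a single condition there was no test between groups, and errors are SDs over the 2 replicates.

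The rule for naming regions without a usable annotation was to take the 10 shared regions with the largest mean fold of both replicates. That rule, the overlap and agreement measures and the alternatives to them on thresholds, overlap, list length and measure were chosen before the data were examined. The distribution along chromosomes, the strongest region of each chromosome, spacing, dense windows and scaffolds were chosen afterwards. Each chromosome was measured from position 1 to the end of its last peak in either list, and its outer quintiles are the 20% at each end, 40% in all. An exact two-sided binomial test asked whether more of the 20 chromosomes lay above 40% than below it.

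Positions are 1-based and given as in the deposited files. The only gene table used here has coordinates of assembly 4.0 of the Williams 82 genome. On 4 chromosomes, peaks lay more than 100 kb beyond the last gene of that table, and on 6 the last peak was more than 1 Mb short of it, so the table was taken to belong to another build. None of its coordinates was used. Binding relative to genes, the count of genes with a promoter peak, the 18 gene lists, the motifs and the named genes planned beforehand were not analysed here.

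The overlap and pileup computations were tested on simulated data before use. All 4984 simulated pileups were recovered (100%), 100% of 28416 planted shared peaks were found, and 0% of 18868 peaks without a partner were reported as shared. The planted peaks were copies of replicate 1 peaks moved by less than the smallest peak width, and the partners of the others were left out. The shares of shared peaks therefore check only that the code runs as written. Simulated backgrounds all lay below 30 fragments, so higher ones were not covered. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9. Alternatives covered stricter −log10 q thresholds of 5 and 10, a reciprocal overlap of 50%, summits within 100 bp, lists of equal length, other measures of strength, local shifts of 10 to 100 kb, the 20 chromosomes without scaffolds, and lists without peaks whose local background exceeded 30 fragments.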

Results

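Binding of the soybean protein GLYMA.13G317000 was mapped in embryos at the early maturation stage. The peak names carry BZIP67, which was taken to be the same protein. Transcription factors with a basic leucine zipper, the class that name refers to, bind DNA as dimers, commonly at sequences with an ACGT core. The series addressed where in the genome this protein is bound in the maturing embryo. It holds 2 ChIP and 2 input libraries, and peaks were given for both ChIP replicates. Input was the only control, so signal from other proteins that the antibody may recognise cannot be told apart. Replicate 1 had 47284 peaks, which covered 18.8 Mb, and replicate 2 had 30289 peaks, which covered 11.1 Mb. Median peak widths were 355 bp and 332 bp. Median fold over local background was 4.78 in replicate 1 and 4.90 in replicate 2, with maxima of 35.0 and 39.1. The median summit rested on 52 fragments in replicate 1 and 44 in replicate 2, and no summit rested on fewer than 19.

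The first comparison asked which sites were bound in both replicates. Almost every site of the smaller list was found again: 29305 of the 30289 peaks of replicate 2 (96.8%) overlapped a peak of replicate 1. In the other direction, 28964 of the 47284 peaks of replicate 1 (61.3%) overlapped a peak of replicate 2. Shifted lists gave 3.89% ± 0.386 (SD over 1000 shifts) and 2.498% ± 0.246 by chance. No shift reached the observed shares, and both had a one-sided permutation p of 0.001, the smallest that 1000 shifts can give. Shifts of only 10 to 100 kb, which keep the local density of peaks, gave 6.89% and 4.43%. After merging, 28903 of 48207 regions held peaks of both replicates, 18320 held peaks of replicate 1 alone and 984 of replicate 2 alone.

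Recovery rose with the strength of binding. Among the weakest decile of replicate 1 peaks, with folds of 1.31 to 3.01, 16.0% were found in replicate 2 (Wilson 95% interval 15.0 to 17.1%). In the fifth decile this was 55.1% (53.7 to 56.5%), and in the eighth, from a fold of 6.62 upward, 98.2% (97.7 to 98.5%). All 4729 peaks of the strongest decile, with folds of at least 11.3, were found in replicate 2. For replicate 2, 83.9% of the weakest decile were found in replicate 1 (82.5 to 85.1%), and 100% in each of the 4 strongest deciles. The weakest deciles mix 2 kinds of peaks, since peaks with a local background above 30 fragments had median folds of only 1.81 and 2.08. In replicate 1, 217 of these were shared and 6 were not, which raises the share of the weakest decile. In replicate 2, 199 were shared and 204 were not, which lowers it. Peaks of replicate 1 without a partner had a median fold of 3.50 and a median pileup of 37 fragments, against 6.51 and 73 for shared peaks. The strongest site of replicate 1 without a partner lay on chromosome 10 from 4251274 to 4251685, with a fold of 8.75 and a pileup of 76 fragments. For replicate 2 it lay on chromosome 11 from 364828 to 365102, with a fold of 5.47 and a pileup of 46. These sites were singled out after their values were seen.

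**Figure D1:**
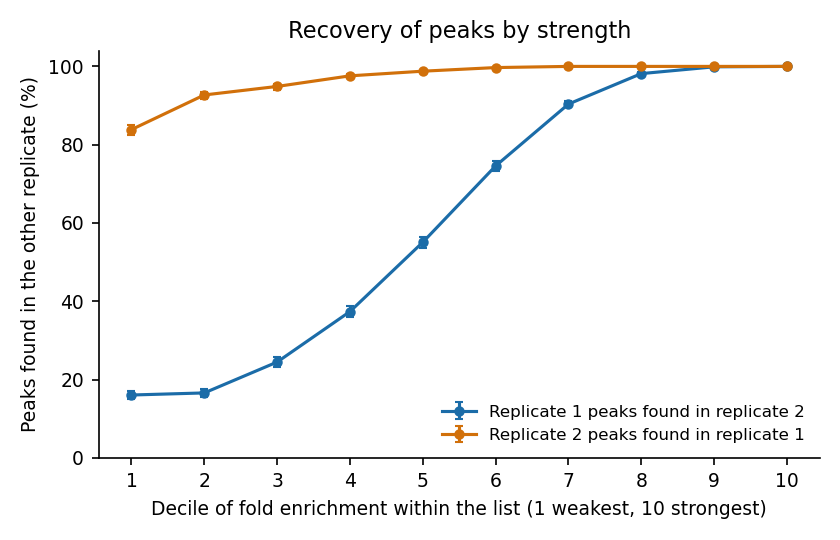
Share of peaks found in the other replicate (%, y axis) by decile of fold within each list (x axis, 1 weakest to 10 strongest), for replicate 1 (blue) and replicate 2 (orange); points are shares with Wilson 95% intervals. Replicate 1 rises from 16.0% to 100%, and replicate 2 from 83.9% to 100%.

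Strength was compared next, over the 28903 shared regions. Regions strongly bound in one replicate were strongly bound in the other, with a Spearman correlation of 0.832 and a Pearson correlation of 0.864 for the log2 fold across regions. Summits lay a median of 22 bp apart, 81.7% lay within 50 bp and 95.5% within 100 bp. In the strongest decile of regions, with mean folds of at least 12.02, the median distance was 13 bp, against 37 bp in the weakest decile. The stronger regions were also wider, with a median of 619 bp against 334 bp. Fold was lower in replicate 2 in 81.0% of shared regions, with a median ratio of 0.806 (quartiles 0.680 and 0.951). The median ratio of pileups was 0.639, below the ratio of the background floors of 0.885. The median SD of a region's fold over both replicates was 16.7% of its mean.

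**Figure D2:**
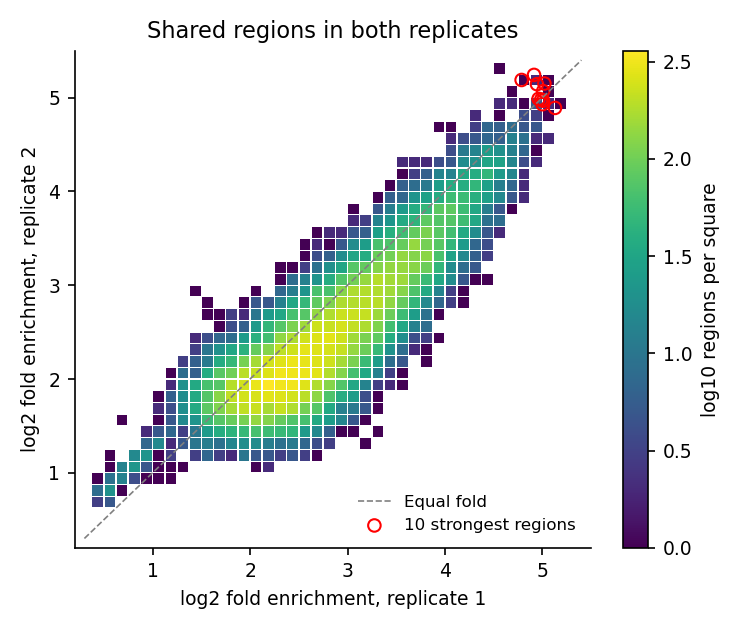
Log2 fold of shared regions in replicate 1 (x axis) and replicate 2 (y axis); colour gives the log10 number of regions per square, red circles the 10 strongest regions and the dashed line equal folds. Most regions lie under the line, as 81.0% had a lower fold in replicate 2.

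The 10 regions with the largest mean fold lay on 8 chromosomes and had mean folds of at least 31.2 (n = 2 for each mean and SD). The first, on chromosome 1 from 8097179 to 8098324, had folds of 30.1 in replicate 1 and 37.9 in replicate 2 (SD 5.45), with pileups of 301 fragments (exact Poisson 95% interval 268 to 337) and 274 (243 to 308). Its summits, at 8097587 and 8097585, were 2 bp apart. The region on chromosome 5 from 7031505 to 7032332 had a mean fold of 33.99 ± 2.18 and pileups of 351 and 286 fragments. A region on chromosome 11 from 2852676 to 2853714 reached 33.1 ± 3.23, and another on chromosome 3 from 36005688 to 36006382 reached 32.9 ± 0.990. Chromosome 8 held 3 of the 10. These lay from 21316513 to 21317359 with 32.3 ± 3.77, from 3808057 to 3808896 with 31.7 ± 0.602, and from 16773486 to 16774376 with 31.2 ± 1.07. On chromosome 16, the region from 13050110 to 13051158 had 32.0 ± 6.27 and the highest pileups of the 10, at 378 and 336 fragments. The remaining regions lay on chromosome 18 from 55165816 to 55166722, with 31.6 ± 0.125, and on chromosome 7 from 2730387 to 2731186, with 31.4 ± 0.406. With SDs of up to 6.27, the order among these regions is not resolved. If only 1 read had been kept per position and strand and read starts were random, the pileups of these 10 regions would stand for a median of 2.12 times as many reads in replicate 1 and 1.76 times in replicate 2, against 1.07 and 1.06 over all peaks, so their folds would be understated. Which genes lie at these positions was not analysed here, since the gene table was taken to belong to another build.

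Each chromosome had at least 1 strongly bound region. The strongest shared region per chromosome ranged in mean fold from 24.9 ± 3.56 on chromosome 19, from 4499505 to 4500195, to the region on chromosome 1 given above. On chromosome 4, the region from 11188644 to 11189492 had the highest fold of either list, 39.1 in replicate 2, but 23.3 in replicate 1, a mean of 31.2 ± 11.2. On chromosome 14, from 6718248 to 6719090, the replicates lay closest together, with folds of 31.1 and 31.0. The chromosome 13 maximum, from 13161691 to 13162501, was 30.4 ± 0.945. On chromosome 18, the named region had a neighbour from 55169019 to 55170014 with a mean fold of 30.5 ± 2.70, at a gap of 2296 bp. It was the only pair within 10 kb among the 100 strongest regions. Random sets of 100 shared regions gave a mean of 0.237 such pairs and as many in a share of 0.213 (one-sided permutation p, 10000 draws), so this pair was within chance.

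Shared regions were concentrated toward the chromosome ends. The outer quintiles of the 20 chromosomes held 19668 of 28745 shared regions, or 68.4%, where an even spread would give 40%. Density was 51.9 regions per Mb in the outer quintiles and 16.0 per Mb between them, a ratio of 3.25. The share was above 40% on 19 of 20 chromosomes (exact two-sided binomial p = 4.01e-05), with a maximum of 85.6% on chromosome 4. By deciles of chromosome length, density fell from 58.8 per Mb in the first to 8.10 per Mb in the sixth and rose to 59.7 per Mb in the tenth. Strength did not follow this gradient: the median of the mean fold was 5.74 in the outer quintiles and 5.78 between them. The share was 68.2% for all replicate 1 peaks and 68.3% for all replicate 2 peaks.

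Chromosome 13 was the exception, with 33.4% of its regions in the outer quintiles. Its sparsest decile was the second, with 4 regions, and its first decile held 31, while each of its last 7 deciles held at least 178. On the other chromosomes, the sparsest decile lay between the fourth and the seventh. Chromosome 13 also had the highest density, with 2079 shared regions, or 45.4 per Mb, followed by chromosome 11 with 41.4 and chromosome 17 with 38.2. Chromosome 18 had the lowest, at 23.1 per Mb, and the whole set averaged 30.3 per Mb over 948 Mb. Densities ordered the chromosomes alike in both replicates, with a Spearman correlation of 0.989 over the 20 chromosomes, which are not independent replicates.

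**Figure D3:**
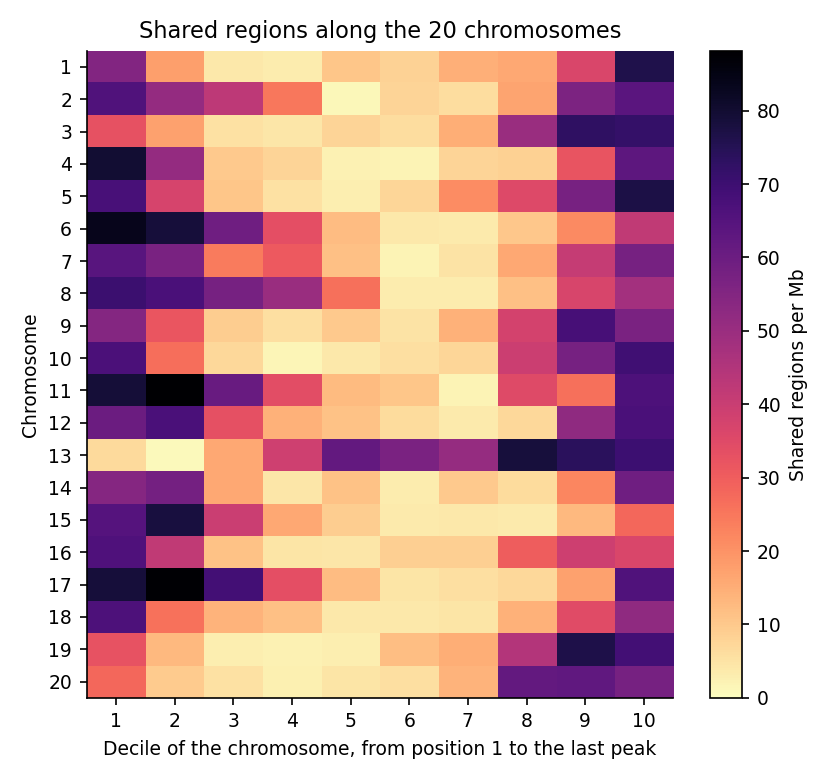
Shared regions per Mb (colour) in deciles of each chromosome (x axis, from position 1 to the last peak) for the 20 chromosomes (y axis). Most chromosomes are dense at both ends, while chromosome 13 is sparse in its first 2 deciles, with 31 and 4 regions.

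At a finer scale, the most densely bound 100 kb window lay on chromosome 9 from 42700001 to 42800000, with 20 shared regions and a highest mean fold of 11.9. The next was on chromosome 11 from 33300001 to 33400000, with 18 regions. Windows with 17 regions included 1 on chromosome 4, 2 on chromosome 6 and 1 on chromosome 12. The list was cut within this tie, in chromosome order, so chromosome 12 and later ones may hold more. Among the windows listed, the one on chromosome 12 from 3400001 to 3500000 had the highest median of the mean fold, 8.48. The mean over all 9494 windows was 3.03 regions, and 3144 windows (33.1%) had none. The longest stretches between neighbouring shared summits ran from 13791705 to 16636790 on chromosome 10 (2.85 Mb), from 13737216 to 16567045 on chromosome 20 (2.83 Mb) and from 23806654 to 26505396 on chromosome 4 (2.70 Mb).

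A small class of peaks had a high local background. It exceeded 30 fragments at 223 peaks of replicate 1 (0.472%) and 403 of replicate 2 (1.33%), with median folds of 1.81 and 2.08 against 4.79 and 4.95 at the other peaks. Of those in replicate 2, 204 had no partner in replicate 1 and made up 20.7% of the 984 unshared peaks of that list. Examples recurred in both replicates on chromosome 12 near 39184545 and 39191579 and on chromosome 13 near 7358806, each with a pileup of at least 392 fragments and folds of 1.87 to 2.30. No summit of either list passed 408 fragments in replicate 1 or 398 in replicate 2. The 10 highest folds of replicate 1 had pileups of 71.3 to 93.4% of that maximum, and those of replicate 2 had 63.6 to 84.4%.

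**Figure D4:**
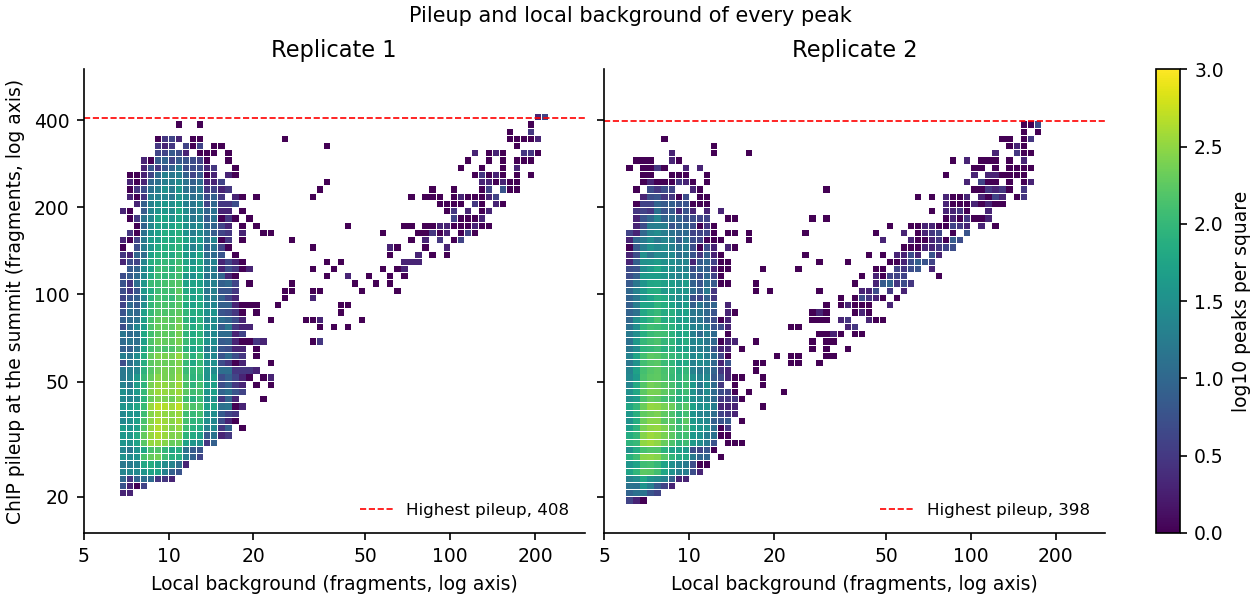
ChIP pileup at the summit (y axis, fragments, log axis) against local background (x axis, fragments, log axis) in replicate 1 (left) and replicate 2 (right); colour gives the log10 number of peaks per square and the dashed line the highest pileup. A separate band of peaks with a background above 30 fragments runs up to the highest pileups of 408 and 398.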

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

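Local shifts, the lists without scaffolds or high-background peaks, pileup as a measure and the distribution along chromosomes were tried only after seeing the data. The share of replicate 2 peaks found in replicate 1 stayed between 86.2% (equal list lengths) and 97.8% (−log10 q of at least 10), and that of replicate 1 peaks between 57.7% (reciprocal overlap of 50%) and 84.9% (equal list lengths), each above all shifts. The number of shared peaks, 28964, went down to 20559 at a −log10 q of at least 10. The Spearman correlation of 0.832 became 0.828 at a −log10 q of at least 5, 0.837 with 50% reciprocal overlap, 0.875 with −log10 p and 0.905 with pileup in place of fold; the cause was not tested. The share in the outer quintiles stayed between 68.2 and 68.6% in every alternative run, each replicate alone included. Of the 10 strongest regions by mean fold, 8 were also among the 10 strongest by −log10 p, 6 by the fold of replicate 1 alone, 5 by that of replicate 2 alone and 0 by pileup. The highest pileups lay at high-background peaks with low folds, such as 408 fragments with a fold of 1.88 in replicate 1. No paired analysis was possible because no test compares groups of libraries, and the input enters only as the local background of each ChIP peak. Alternatives for promoters, genes, gene lists and motifs were not run, for want of an annotation and genome of the files' build. Read totals were not known, so a site with a peak in 1 replicate alone cannot be called unbound in the other.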

Other observations

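The spacing of regions, scaffolds and the limit on the pileup were chosen only after the data were seen. So were the step and level of the unscaled input and the second level in the test of unshared peaks. The comparison over all replicate 1 peaks was not fixed beforehand. The other tests below were fixed before their results. Neighbouring shared regions were closer than random placement within the same 1 Mb bins gave. Between 500 and 1000 bp, 1230 pairs of adjacent summits were found against 740 ± 25.6 (SD over 100 draws), a ratio of 1.66. Between 1000 and 2000 bp there were 2476 against 1403 ± 34.8, a ratio of 1.76. From 5000 to 10000 bp the ratio was 0.985. Distances under 500 bp, with 79 pairs against 764, are limited by peak width, since overlapping peaks are merged. Random placement had no such limit, which may raise the ratios of the ranges next to it. It was also even within each bin, and in the last bin of a chromosome it could pass the end. Both may lengthen the random distances, so closeness was not told apart from uneven density within 1 Mb. The median distance over all adjacent summits was 11639 bp against 13852 ± 86.4 bp at random.

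Shared regions also lay outside the 20 chromosomes, with 158 on 37 scaffolds. Scaffold 21 held 56 of them, scaffold 28 held 21 and scaffold 32 held 15. The strongest, on scaffold 21 from 3534298 to 3534903, had a mean fold of 21.0 ± 3.14 (n = 2), and the next, from 3067486 to 3068139, had 20.2 ± 1.80. Not all of the 158 need mark binding. A high-background region on scaffold 2080 had pileups of 408 and 398 fragments but folds of only 1.88 and 2.30 in replicates 1 and 2.

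The 18320 peaks of replicate 1 without a partner left 61.3% of its peaks found in replicate 2, and this share was set against what the depth and enrichment of replicate 2 would allow. At the depth ratio of 0.885 alone, 97.7% of all replicate 1 peaks would be expected to pass the lowest −log10 p of replicate 2 (3.93). The level of 7.28 that 95% of its peaks exceed would be passed by 87.5%. Both shares were above the share found. Each pileup was taken as its true mean although peaks had been picked for a high pileup, which raises every expected share. Depth as the whole cause was therefore not decided. With the pileup ratio of the strongest quintile (0.626), which includes weaker enrichment, the expected shares were 82.7% at the lowest level and 61.2% at the second. Among the unshared peaks alone, the expected shares at the lowest level were 94.7% for depth and 63.6% with the pileup ratio. Both were past the limit that had been fixed beforehand as counting against each explanation. At the second level the expected shares were 72.5% for depth and 25.9% with the pileup ratio. Peaks picked for not being found must fall short of any such model, so these values decide little. Weaker enrichment in replicate 2 is a candidate explanation that meets the share found at the second level and not at the lowest. At the second level, 83.6% of the shared peaks would be expected to pass with the pileup ratio, so the match concerns the total only. This explanation stays open because that level was chosen after the data were seen, and no biological explanation was tested.

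The highest pileup was exactly 2 times the smallest peak width in both replicates, the value that 1 read kept per position and strand would give if that width were the fragment length. Under such a limit a deep input may saturate and lower the fold. With evenly spread read starts and no enrichment at all, the observed pileup of high-background peaks was 1.52 and 1.76 times the prediction in replicates 1 and 2. Both ratios were past the limit fixed beforehand as counting against this explanation. However, peaks had been picked for a pileup above their background, which raises these ratios, and some enrichment would do the same. Saturation with evenly spread read starts was therefore not decided. The input before scaling was not measured but inferred from steps of the background: 408 and 398 steps in the highest background made 94.1% and 98.8% of the other high backgrounds whole numbers of steps (tolerance 0.02), against at most 45.9% and 54.7% for step numbers that are no multiple of these. If reads start at the same uneven positions in ChIP and input, the pileup approaches that unscaled input, and the median ratios were 0.966 and 0.911, or 0.967 and 0.912 at the 196 and 363 peaks where the limit left room for a higher ratio. This ratio restates the low fold in units of the input, so saturation at uneven positions stays open as a candidate explanation, and the quartiles of 0.852 to 1.14 and 0.813 to 0.993 show that it would not account for each of these peaks alike.

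For the sparse middle of the chromosomes, weaker peaks falling under the threshold would leave fewer strong than weak peaks there. The inner share was 32.0% in the strongest quintile of replicate 1 peaks and 31.6% in the weakest, a ratio of 1.01. This argues against it among the peaks that passed the threshold. Sites under the threshold were not seen, so a weakening that left the spread of folds above it alike was not excluded. Peaks between the outer quintiles lay more often at the background floor, with odds ratios of 3.50 (Fisher's exact two-sided p = 3.52e-45) and 2.48 (p = 5.84e-35) across peaks, which are not independent replicates. A loss of mappable reads may contribute, but the floor held only 2.17% and 4.30% of those peaks, and median backgrounds between and in the outer quintiles were 9.74 and 10.1 in replicate 1 and 7.81 in both parts in replicate 2. Gene density, which could also shape the gradient, was not tested, since no annotation of the files' build was used here.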
